A study of Homo sapiens with 5 samples.

How the data were processed

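RNA of single cells was measured in 3 macroVET libraries with the 10x Genomics 3' protocol, per the labels. The values used were raw UMI counts per gene and cell barcode, deposited as a matrix per library with lists of barcodes and of 36601 genes. Per the submitters' processing notes, Cell Ranger 7.1.0 and the genome build GRCh38 were used for the macroVET samples and Cell Ranger 9.0.0 for the other 2 samples; which step each served, and whether intronic reads were counted, is not given in the sources used here. The matrices held whole numbers, and their barcodes were the ones listed, so the counts were taken as not normalized. The samples of 2D valve cells and of 3D tissue were used only as barcode and gene lists, with the same 36601 genes, and no expression in them was analysed here.

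Cells were kept with at least 1000 UMIs, at least 500 genes and a mitochondrial share of UMIs under 15%. For replicates 1, 2 and 3, 88, 86 and 136 barcodes failed the UMI or gene minimum and 223, 219 and 289 the mitochondrial limit. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 0.05, called 14, 14 and 36 doublets (0.935%, 1.02% and 1.78%), which were left out. The kept cells held 36230128, 38243943 and 50774956 UMIs, with a median mitochondrial share of 5.28%, 4.45% and 5.02%.

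Genes were divided before the clustering, so that no gene was tested that had helped to form the groups. Genes of both parts can vary together in the same cells, so the division does not free the tests from the clustering. The clustering part held 18207 genes, among them all 151 markers of 16 cell classes, and the testing part 18278 genes, among them all 386 genes of 17 lists. Mitochondrial and ribosomal protein genes, 116 in all, were in neither. Markers, lists, filters, the main tests and most alternatives were set before the data were examined, and those chosen later are named as such below. Cells of the 3 libraries were clustered together without integration, since the labels put them in 1 batch: counts per 10000 with log1p, 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5 (leidenalg 0.10.2, igraph 0.11.9).

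A marker counted as present in a cluster if at least 25% of its cells had a UMI, its level reached 10 CPM and it was at least 3 times the 25th percentile over clusters. A cluster took the class with the most markers present, if these were at least 3 and no other class had as many. A cluster stayed unnamed if at least 2 of its 10 leading genes (clustering part, by fold against the other cells) were markers of another class and more than of its own. It also stayed unnamed if its median UMI number was low in every library and none of its leading genes was a marker of its class. Cluster 10, with a median of 6303 UMIs, was low by this measure against replicate 2 only and kept its class. This naming rule was settled after the clusters were seen, and the number of 2 leading genes after it was seen that 1 would leave clusters 3 and 7 unnamed. Cycling was treated as a state, not a class. The names describe marker patterns and not the origin of the cells.

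For each class or cluster the UMIs were summed per library, with classes of at least 20 cells in every library compared. The immune-like and epithelial-like classes were compared with the fibroblast-like class, which held the most cells when the libraries were pooled, though not in replicates 1 and 3 and not with clusters 3 and 7 left out. Its 3 largest clusters were each compared with the remaining cells of the class. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (limma 3.58.1), with filterByExpr, TMM scaling and the library as a block, since both sides came from the same libraries. TMM sets aside the most abundant and most changed genes, so fold changes differ from the ratios of the printed CPM. Against library totals it moved the median log2 fold change of the tested genes by -0.265 and -0.415 in the immune-like and epithelial-like comparisons and by 0.0446, 0.0410 and 0.367 for clusters 1, 2 and 3. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Lists were tested with camera at its preset correlation and with Benjamini-Hochberg adjustment over the 17 lists. Each list also had its members past the threshold counted, both over all tested genes and adjusted over the list alone. Levels are CPM of summed UMIs, given as mean ± SD over libraries, and log2 fold changes carry the SE of the fit. For genes with 0 UMIs on a side, the fold is a lower bound against 3 UMIs over the group, and with 1 to 3 UMIs a ratio with its exact 95% interval is given.

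Genes named in a comparison followed a rule set beforehand. From each list these were up to 2 members past the threshold with the largest absolute log2 fold change, among those at 10 CPM or more on a side and changed the same way in all 3 libraries. Outside the lists they were the 5 highest and 5 lowest genes past the threshold with at least 50 CPM on a side and a symbol that is not a clone name. For tissue levels they were the 3 most abundant genes of each list and a fixed set of markers. Names outside this rule, such as leading genes of clusters, MRC1, CD163, CSF1R, PECAM1 in the classes, SAA1, SLPI, ALB and MALAT1, were chosen after their values were seen. Some genes that the rule names are not reported here. Gene coordinates came from GENCODE v29 on GRCh38, where 8861 of 9015 gene identifiers matched (98.3%).

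The share of cells with MKI67 or TOP2A was counted after thinning each cell to 5781 UMIs, the 10th percentile of kept cells. The tests were tested on simulated data made from these counts with changes of known size at 2-fold and 4-fold. At most 100 genes were changed at each size, in 1 simulation per comparison, and all others were set equal between the sides. Far more genes were called in the real comparisons, so the shares below hold for the simulated setting. In the comparisons of the immune-like and epithelial-like classes and clusters 1, 2 and 3, 76.8%, 31.9%, 80.6%, 84.0% and 78.8% of genes changed 2-fold were recovered. Of genes changed 4-fold, 96.0%, 71.4%, 99.0%, 98.0% and 95.0% were recovered. The alternatives set beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter, no replicate block, each replicate left out, clustering at resolution 0.3 and 1.0, another division of the genes, centring per library, mitochondrial limits of 10% and 25%, doublets kept, camera with an estimated correlation, fry, the mean over cells, 2 UMIs instead of 1, and no thinning. Chosen after seeing the data were library totals instead of TMM scaling, the inclusion of clusters led by genes of another class, the exclusion of clusters with 1 such gene, and the exclusion of clusters 10 and 16. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.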

Results

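Bioengineered human heart valve tissue was profiled by droplet-based single-cell RNA sequencing after 30 days of 3D culture. The tissues, called macroVETs (a form of valve engineered tissue), were made from valve cells derived from HES3, an established human embryonic stem cell line. Their medium held 10% serum together with dexamethasone, a synthetic glucocorticoid, ascorbic acid, which collagen hydroxylation needs, proline, and a supplement of insulin, transferrin and selenium. Cells were freed from the tissue with a dissociation kit and sorted by flow cytometry before 3' libraries were made. The gate of that sort is not given in the sources used here. 3 macroVET libraries of 1 batch were analysed as replicates 1, 2 and 3. They held 1733, 1623 and 2366 cell barcodes with 38005375, 39895228 and 53798424 UMIs (unique molecular identifiers, each marking 1 captured transcript). After filtering, 1483, 1363 and 1989 cells remained, with medians of 15692, 23787 and 16879 UMIs and of 4269, 4933 and 4365 genes per cell. No pair of libraries was a duplicate: pairs shared 0 barcodes, and their counts differed by more than the counting noise of UMIs. The chi-square per degree of freedom was 24.4 to 54.7. UMIs of the same cell are not independent, so these values do not cover the noise of drawing different cells. Across genes, which are not independent replicates, log2 CPM (counts scaled to the same library total of 1e6) of the pairs correlated at r = 0.989 to 0.992. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. A sample titled as 2D valve cells (21873 barcodes), whose growth protocol nevertheless describes 3D culture, and another sample of 3D tissue (17432 barcodes) were used here only as lists of barcodes and genes, and 2D and 3D culture were not compared.

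The level of each transcript in the tissue was taken from the pooled cells of each library, as mean ± SD over n = 3 libraries. Cells with more UMIs weigh more in such pools, and 47 of 73 levels moved by 1 SD or more when taken as means over cells. TIMP1, an inhibitor of matrix metalloproteinases, stood at 5993 ± 506 CPM, VIM, an intermediate filament of mesenchymal cells, at 2299 ± 340 CPM, and SPARC, a matrix-binding glycoprotein, at 1266 ± 98.8 CPM. Among the collagens, COL1A1 reached 1319 ± 223 CPM, COL3A1 1161 ± 225 CPM, COL6A2 344 ± 11.6 CPM and COL11A1 217 ± 31.1 CPM. The small leucine-rich proteoglycans LUM and DCN stood at 636 ± 31.8 and 194 ± 30.2 CPM, the heparan sulfate proteoglycan GPC6 at 515 ± 90.9 CPM and VCAN, the large proteoglycan of the valve spongiosa, at 45.7 ± 19.7 CPM. The microfibril gene FBN1 reached 402 ± 49.1 CPM and FBLN5 204 ± 22.3 CPM, while ELN, which encodes elastin, stood at 11.2 ± 1.61 CPM. Of glucocorticoid response genes, MT2A stood at 5316 ± 574 CPM, CEBPD at 1696 ± 267 CPM, TSC22D3 at 732 ± 107 CPM and FKBP5 at 724 ± 9.03 CPM. Of genes tied to calcification, PDPN reached 1150.5 ± 279 CPM, MGP, an inhibitor of calcification, 389 ± 131 CPM, and RUNX2, an osteogenic transcription factor, 98.4 ± 13.3 CPM. Transcription factors of valve development included FOXP1 at 409 ± 107 CPM, SOX4 at 213 ± 16.7 CPM, MEIS2 at 206 ± 40.3 CPM, TBX20 at 27.4 ± 1.22 CPM and NFATC1 at 24.8 ± 3.13 CPM.

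Abundant members of other lists were RBPJ (261 ± 50.5 CPM) among Notch genes, TCF7L2 (133 ± 13.4 CPM) among Wnt genes and CALD1 (1043 ± 75.3 CPM) among YAP and mechanosensing genes. B2M (1926 ± 90.3 CPM) led the interferon and inflammation list, GAPDH (1189 ± 142 CPM) the hypoxia and glycolysis list, HSP90AA1 (711 ± 43.1 CPM) the immediate-early and heat-shock list, TFPI (451 ± 100.1 CPM) the endothelial haemostasis list and PCNA (18.9 ± 1.57 CPM) the DNA replication list. The contractile genes ACTA2 and TAGLN stood at 129 ± 5.09 and 273 ± 57.2 CPM and POSTN at 38.1 ± 7.13 CPM. Low levels were found for the cartilage genes SOX9 (6.31 ± 1.86 CPM) and ACAN (0.599 ± 0.177 CPM), the endothelial cadherin CDH5 (0.673 ± 0.564 CPM, or 0.347 CPM without replicate 1, where it stood at 1.32 CPM) and the pluripotency factor POU5F1 (0.296 ± 0.0892 CPM). The 3 UMIs used as the floor of detection corresponded to 0.0591 to 0.0828 CPM in a library, and such floors cover counting error only.

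Which cell classes made up the tissue was read from 17 clusters, named from markers fixed beforehand. Fibroblast-like cells (clusters 1, 2, 3, 7, 8 and 10), with COL1A1, COL3A1, DCN, LUM and PDGFRB present in each cluster, made up 46.8% ± 9.54 of the cells (SD, n = 3 libraries; 40.5%, 57.8% and 42.2%). Immune-like cells (clusters 0, 4, 5, 15 and 16), which carried CD68, TYROBP and AIF1 in each cluster and PTPRC, CD14 and LYZ in all of these clusters but 16, made up 40.6% ± 9.17 (47.1%, 30.1% and 44.4%). In this class MRC1, the mannose receptor of macrophages, stood at 1361 ± 131 CPM, the haemoglobin scavenger receptor CD163 at 1124 ± 149 CPM, and CSF1R, the receptor that macrophages need for survival, at 499 ± 52.2 CPM. Epithelial-like cells (clusters 12 and 13), marked by EPCAM, CDH1, KRT8, KRT18, KRT19, CLDN4, ESRP1 and GRHL2, made up 2.56% ± 0.776 (2.36%, 1.91% and 3.42%), or 4.28% with doublets kept, which added 64 cells in all but 84 to this class, so part of that rise was a change of names. Cells of 4 unnamed clusters made up 10.0% ± 0.134, an SD that leaves out the naming, since the share was 7.99% to 20.3% under other settings of clustering and filters. Cluster 6 (5.27%) had 9 fibroblast markers but was led by the troponins TNNT2 and TNNI1 together with THY1, and cluster 9 (2.08%) was cycling and led by the smooth muscle genes ACTG2 and TAGLN. Cluster 11 (1.72%) had as many smooth muscle and epithelial markers as fibroblast markers, but 5 of its 10 leading genes were markers of another class. Its leading genes included ALB, APOA1, APOA2, TTR and AFP. Most of its cells had no UMI of each: APOA1 was found in 27.16%, AFP in 19.753% and ALB in 2.4691% of them. Cluster 14 (0.967%) had a median of 2280 UMIs and fewer than 3 markers of any class. Clusters 3 (9.47% of cells) and 7 (5.18%) were led by 1 gene of another class each, COMP and MYH6. MYH6 had a UMI in only 0.837% of the cells of cluster 7, with 0, 1 and 514 UMIs per library, so very few cells made it a leading gene. These clusters stayed in the fibroblast-like class only because the naming rule, settled after the clusters were seen, allowed 1 such gene. The acute-phase gene SAA1 and the antiprotease gene SLPI were among the leading genes of cluster 3. Depth differed between the classes, with medians of 36194 UMIs in fibroblast-like, 8781 in immune-like and 14883 in epithelial-like cells, and the sort and the filters can set shares of this kind.

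**Figure D1:**
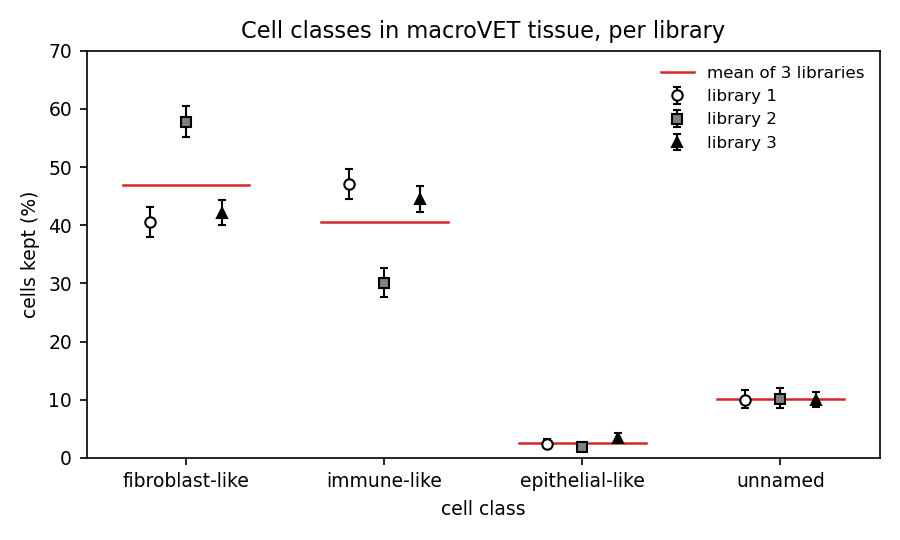
Share of kept cells (percent, linear axis) in each cell class for the 3 macroVET libraries, with exact 95% binomial intervals as error bars and the mean as a red line. Library 2 held 57.8% fibroblast-like and 30.1% immune-like cells, while the other two held 40.5% and 42.2% fibroblast-like and 47.1% and 44.4% immune-like cells.

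No cluster was named endothelial, although the valve surface is endothelial in the body. 10 of 4835 cells carried at least 3 of 6 endothelial markers, a share of 0.207% (exact 95% binomial interval 0.0992% to 0.380%, counting error only). PECAM1, which macrophages also express, stood at 75.3 ± 4.74 CPM in immune-like cells and 0.693 ± 0.107 CPM in fibroblast-like cells, while CDH5 stood at 0.0415 ± 0.0719 and 0.431 ± 0.00923 CPM. At least 3 of 6 cardiomyocyte markers were found in 84 cells (1.74%, interval 1.39% to 2.15%) and at least 3 of 6 gut or hepatic endoderm markers in 19 cells (0.393%, interval 0.237% to 0.613%). A sole cell held 1917 of the 2011 ALB UMIs of the dataset (95.3%), and 36 cells held at least 1. With libraries pooled, ALB stood at 1593.2 CPM in the unnamed cluster 11 and 0.74973 CPM in all other cells.

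Cycling cells were counted by MKI67 and TOP2A, which are transcribed in dividing cells, after each cell was thinned to 5781 UMIs. Shallower cells were left out, 142, 105 and 237 per library. MKI67 was found in 2.19% ± 0.402 of cells (SD, n = 3 libraries; 1.40% at 2 UMIs and 3.07% without thinning) and TOP2A in 3.29% ± 0.636 (1.78% at 2 UMIs and 6.27% without thinning). By class, MKI67 was found in 3.14% ± 0.815 of immune-like and 0.202% ± 0.18 of fibroblast-like cells, and in 3.62% ± 3.57 of epithelial-like cells, where 4 cells in all carried it. As a measure of background at the same depth, PTPRC, a leukocyte gene, was found in 72.4% ± 1.35 of immune-like and 0.355% ± 0.296 of fibroblast-like cells, and COL1A1 in 85.8% ± 6.32 of fibroblast-like and 10.6% ± 4.80 of immune-like cells. PTPRC and COL1A1 were in the clustering part and served as markers, so their low shares in the other class may understate background. The shares of MKI67 by class also depend on the grouping. Cluster 9, which was cycling with MKI67 in 49.5% of its cells and had 10 fibroblast markers, stayed unnamed and so out of the fibroblast-like class. Cluster 15, an immune-like cluster led by MKI67 and TOP2A, made up 0.964% ± 0.135 of the tissue and was counted in its class, so immune-like and fibroblast-like cells cannot be compared in cycling from these shares.

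The comparison of immune-like with fibroblast-like cells asked how the main populations of the tissue differ in genes that took no part in the clustering. The groups still came from the expression of the same cells. Counts of calls and p-values, here and below, therefore describe the groups and are no evidence for the grouping. CD86, a costimulatory receptor of antigen-presenting cells (ENSG00000114013, chromosome 3, 122055366 to 122121139), stood at 274 ± 29.3 CPM against 0.254 ± 0.135 CPM in fibroblast-like cells, 831-fold higher (log2 fold change 9.70 ± 0.22, SE). CYBB, the catalytic subunit of the phagocyte NADPH oxidase (ENSG00000165168, chromosome X, 37780011 to 37813461), was 646-fold higher, CD84 652-fold, HLA-DMB, a chaperone of peptide loading onto MHC class II, 679.5-fold, and IL1RN, the interleukin-1 receptor antagonist, 822-fold. FBN1 stood at 5.47 ± 2.09 CPM in immune-like and 507 ± 97.6 CPM in fibroblast-like cells, 109-fold lower (-6.76 ± 0.22), and CALD1, an actin-binding regulator of contraction, was 85.7-fold lower (-6.42 ± 0.22). The lowest genes outside the lists included RBMS3, an RNA-binding protein gene (4.26 ± 1.88 against 1115 ± 179 CPM), with CLSTN2, IGSF1 and LINGO2, which were 415-, 348- and 285-fold lower. LINC01695 had 1 UMI in immune-like cells, a ratio of 1235 with a counting interval of 222 to 48783.

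By list, most matrix genes were lower in immune-like cells, and camera called these lists as groups at its preset correlation but not with an estimated correlation. Of 17 collagens 16 were lower and 0 higher, with COL5A2 (ENSG00000204262, chromosome 2, 189031896 to 189225312) 121-fold lower and COL11A1 98.2-fold lower. Of 20 elastic fibre and microfibril genes 18 were lower and 2 higher, and ELN, with 2 UMIs in immune-like cells, had a ratio of 110 (interval 30.4 to 910). Of 16 basement membrane genes 15 were lower and 0 higher, such as NID2, which links laminin to collagen (72.3-fold), and COL4A5 (99.3-fold). Of 20 proteoglycan and hyaluronan genes 16 were lower and 2 higher, with SPOCK1 117-fold lower and HAS2, a hyaluronan synthase, at a ratio of 162 (3 UMIs, interval 55.4 to 787). Of 29 matrix remodelling enzymes 19 were lower and 9 higher, and ADAMTS9, a secreted proteoglycan-cleaving protease, was 186-fold lower. Of 25 valve transcription factors 22 were lower and 3 higher, with NR2F1 at 0.284 ± 0.190 against 75.4 ± 8.27 CPM and TWIST2 at a ratio of 204 (3 UMIs, interval 69.6 to 988). Of 21 Wnt genes 18 were lower and 2 higher, with the Wnt antagonist SFRP1 114-fold lower. Of 20 glucocorticoid response genes 17 were lower and 2 higher, such as CRISPLD2 (57.1-fold). Of 23 YAP and mechanosensing genes 16 were lower and 5 higher, with the matricellular gene CCN1 86.7-fold lower.

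Camera did not call the other 8 lists in this comparison, whereas fry called 7 of these 8, all but the endothelial list. SPP1, osteopontin, which macrophages and bone cells secrete (ENSG00000118785, chromosome 4, 87975650 to 87983426), was higher in immune-like cells (2073 ± 1449 against 8.02 ± 4.49 CPM, 7.62 ± 0.47), whereas ENPP1, which makes the calcification inhibitor pyrophosphate, was 127-fold lower. The neutrophil chemokine CXCL8 stood at 1238 ± 105 against 26.1 ± 9.29 CPM and IFIT3, an interferon-induced gene, was 5.97-fold lower. Of 16 Notch genes 7 were higher, led by the Fringe glycosyltransferases MFNG (127-fold) and LFNG (30.8-fold), and 6 were lower. Of 27 DNA replication and mitosis genes 15 were higher and 1 lower, with CENPA 6.08-fold and RRM2, a ribonucleotide reductase subunit, 13.7-fold higher. These values depend on the grouping, since the cycling cluster 15 was counted as immune-like while the cycling cluster 9 was left out of the fibroblast-like class. With clusters 6 and 9 counted as fibroblast-like, a setting chosen after seeing the data, the log2 fold change of RRM2 was 0.84 instead of 3.78 and that of CENPA 1.83 instead of 2.60. At clustering resolution 0.3 the log2 fold change of RRM2 was 0.50 and no longer passed. Of 28 TGF-beta and BMP genes 18 were lower and 8 higher (TGFBR3 76.1-fold lower). Of 23 hypoxia and glycolysis genes 14 were lower and 8 higher (EGLN3 20.3-fold lower). Of 21 immediate-early and heat-shock genes 13 were lower and 6 higher (HSPB1 9.73-fold lower, EGR2 9.37-fold higher). Of 12 osteogenic genes 8 were lower and 4 higher. Of 14 endothelial haemostasis genes 6 were lower and 6 higher (VCAM1 107-fold lower). Of 21 interferon and inflammation genes 9 were higher and 6 lower.

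In this comparison 6895 of 8597 testing-half genes passed (3266 higher and 3629 lower in immune-like cells; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), from summed counts of 4552214 to 8034640 UMIs per library in immune-like and 23453668 to 35249740 in fibroblast-like cells. With library totals instead of TMM scaling, a setting chosen after seeing the data, 3689 genes were higher and 3207 lower. For CD86 the adjusted p of this edgeR test with Benjamini-Hochberg adjustment was 4.6e-12, and the gene was higher in 3 of 3 libraries. Adjusted over the list alone, 7 instead of 6 endothelial haemostasis genes were lower, and the counts of the other lists were the same. The camera test with its preset correlation called 9 lists, the collagen, elastic fibre, basement membrane, proteoglycan, matrix enzyme, valve transcription factor, Wnt, glucocorticoid and YAP lists, all lower. None of these 9 held with an estimated correlation, where camera gave Benjamini-Hochberg adjusted p = 0.564 with an estimated correlation for 8 of them and adjusted p = 0.621 with an estimated correlation for the matrix enzymes. With 6 sums per comparison and the library as a block, few residual degrees of freedom are left for that estimate. The estimated test thus had little power, here and in the comparisons below, and its lack of calls does not show that lists were unchanged. COL1A2 stood in the immune-like class at 2.22% of its fibroblast-like level. LUM stood there at 1.03%, and LYZ and TYROBP in the fibroblast-like class at 0.162% and 0.363% of their immune-like level, but these 3 genes helped to form the classes.

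The epithelial-like cells, 129 cells in all, were compared with the fibroblast-like cells to describe the smallest named class. Its makeup differed between libraries, with 10, 25 and 37 cells of cluster 12 and 25, 1 and 31 cells of cluster 13. At equal depth EPCAM was found in 66.3% ± 26.5 and COL1A1 in 55.5% ± 27.6 of these cells, with the SD between libraries. COL3A1, which helped to form the clusters, was found in 98.3% ± 2.89 of epithelial-like, 79.9% ± 7.37 of fibroblast-like and, as a measure of background, 14.0% ± 3.62 of immune-like cells (93.7%, 92.0% and 21.3% without thinning). AGR2, a protein disulfide isomerase of secretory epithelia (ENSG00000106541, chromosome 7, 16791811 to 16833433), stood at 436 ± 60.2 CPM against 0.211 ± 0.137 CPM, 1376-fold higher (log2 fold change 10.43 ± 0.32, SE). GABRP, a GABA receptor subunit of epithelial tissues, was 1085-fold higher, CST6, a cysteine protease inhibitor of skin and glands, 373-fold, and DAPP1 and PLSCR5 698- and 634-fold. EDN1, the vasoconstrictor peptide endothelin-1 (ENSG00000078401, chromosome 6, 12290363 to 12297194), was 69.6-fold higher (6.12 ± 0.24; 201 ± 15.2 against 2.21 ± 0.979 CPM). The calcification inhibitor MGP was 315-fold lower (-8.30 ± 0.42), the pentraxin PTX3 175-fold and GNRH2 221-fold. SELENBP1 and the coagulation factor gene F10 had 0 UMIs in epithelial-like cells, at least 111-fold and at least 63.2-fold lower against a floor of 3 UMIs over the group. VTN, vitronectin, with 3 UMIs had a ratio of 173 (counting interval 59.2 to 839).

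Of 20 glucocorticoid response genes 17 were lower in epithelial-like cells and 0 higher, with a median log2 fold change of -2.31. MT2A stood at 133 ± 36.0 against 6948 ± 832 CPM, 71.8-fold lower (-6.17 ± 0.24), and MT1M with 0 UMIs was at least 9.59-fold lower, although its log2 fold change was 1.66 when doublets were kept and the class held 213 cells. Of 25 valve transcription factors 16 were lower and 2 higher, with a median of -2.10, or -1.34 with the genes at 0 UMIs set to their bound. PRRX1 and TBX20, transcription factors of mesenchyme and of the developing heart, had 0 UMIs and were at least 30.6-fold and at least 29.5-fold lower. Of 20 proteoglycan genes 16 were lower and 1 higher (median -2.61, or -2.35 at the bound), with SPOCK1 107-fold lower and FMOD, at 0 UMIs, at least 14.4-fold lower. Of 29 matrix remodelling enzymes 18 were lower and 3 higher (median -1.33, or -1.16 at the bound), with TIMP1 18.4-fold lower (588 ± 193 against 7740.5 ± 549.8 CPM). Of 20 elastic fibre genes 12 were lower and 3 higher (LOX, the collagen and elastin cross-linking enzyme, 37.3-fold lower). Of 16 basement membrane genes 9 were lower and 2 higher (NID1 64.5-fold lower, LAMA4 at 0 UMIs at least 17.3-fold lower). Of 23 YAP and mechanosensing genes 11 were higher and 5 lower, with the kinase gene NUAK2 16.6-fold higher and the stretch-activated channel gene PIEZO2 12.1-fold lower.

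Among lists that camera did not call, 9 of 19 collagens were lower and 5 higher, but 8 lower and 9 higher scaled by library totals (COL11A1 21.1-fold lower; COL8A2 with 2 UMIs at a ratio of 47.7, interval 13.2 to 394). Of 28 TGF-beta and BMP genes 15 were lower, such as ENG (26.6-fold), and 8 higher, such as the BMP antagonist NOG (15.6-fold), but 9 lower and 10 higher scaled by library totals. Of 13 Notch genes 4 were lower and 4 higher (1 and 5 scaled by library totals), with the Notch target HEY1 5.26-fold and the receptor gene NOTCH3 4.16-fold higher; NOTCH3 did not pass without replicate 3 (log2 fold change 1.55). Of 24 Wnt genes 9 were higher and 5 lower (FRZB 109.9-fold lower), and the median (0.14) and the test of this list pointed up while its mean (-0.20) pointed down. The Notch list had a median of 0.18 and a mean of -0.34. Of 23 hypoxia and glycolysis genes 11 were lower and 3 higher, with the glucose transporter gene SLC2A3 7.13-fold higher. Of 20 DNA replication genes 4 were higher and 0 lower (MCM4 4.23-fold), against a fibroblast-like class without the cycling cluster 9. Of 21 immediate-early and heat-shock genes 8 were lower and 3 higher, but 6 and 6 scaled by library totals (FOSL1 4.78-fold higher). Of 11 endothelial haemostasis genes 5 were lower and 3 higher, but 3 and 3 scaled by library totals (VCAM1 with 1 UMI at a ratio of 95.6, interval 17.2 to 3777). Of 20 interferon and inflammation genes 9 were lower and 2 higher (PTGS2 4.88-fold higher). Of 11 osteogenic genes 4 were lower and 2 higher, but 3 and 3 scaled by library totals (PDPN 24.9-fold lower). Camera called this list as lower with library totals (Benjamini-Hochberg adjusted p = 0.0256) and with DESeq2 size factors, but not with an estimated correlation (Benjamini-Hochberg adjusted p = 0.390).

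Here 3263 of 7988 genes passed (1465 higher and 1798 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 1938 passed without replicate 3, which held 68 of the 129 cells. TMM scaling lowered the median log2 fold change of this comparison by 0.415 against library totals, with which 2217 genes were higher and 1094 lower, a setting chosen after seeing the data. The summed counts of epithelial-like cells were 663006, 394087 and 1473588 UMIs. In data simulated at this depth the test recovered 31.9% of genes changed 2-fold and 71.4% of those changed 4-fold, so smaller differences were often missed there. Far fewer genes were changed in that simulation than were called here, so these shares may differ in the real data. Adjusted over the list alone, higher and lower counts became 6 and 9 for collagens, 4 and 18 for matrix enzymes, 11 and 5 for Wnt, 2 and 17 for valve transcription factors, 3 and 0 for DNA replication, 3 and 9 for immediate-early, 3 and 7 for endothelial and 3 and 9 for interferon genes, and stayed the same for the other lists. Camera with its preset correlation called 7 lists, the elastic fibre, proteoglycan, basement membrane, matrix enzyme, valve transcription factor and glucocorticoid lists as lower and the YAP list as higher. None of the 7 held, with adjusted p = 0.377 to 0.390 with an estimated correlation (camera, Benjamini-Hochberg).

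**Figure D2:**
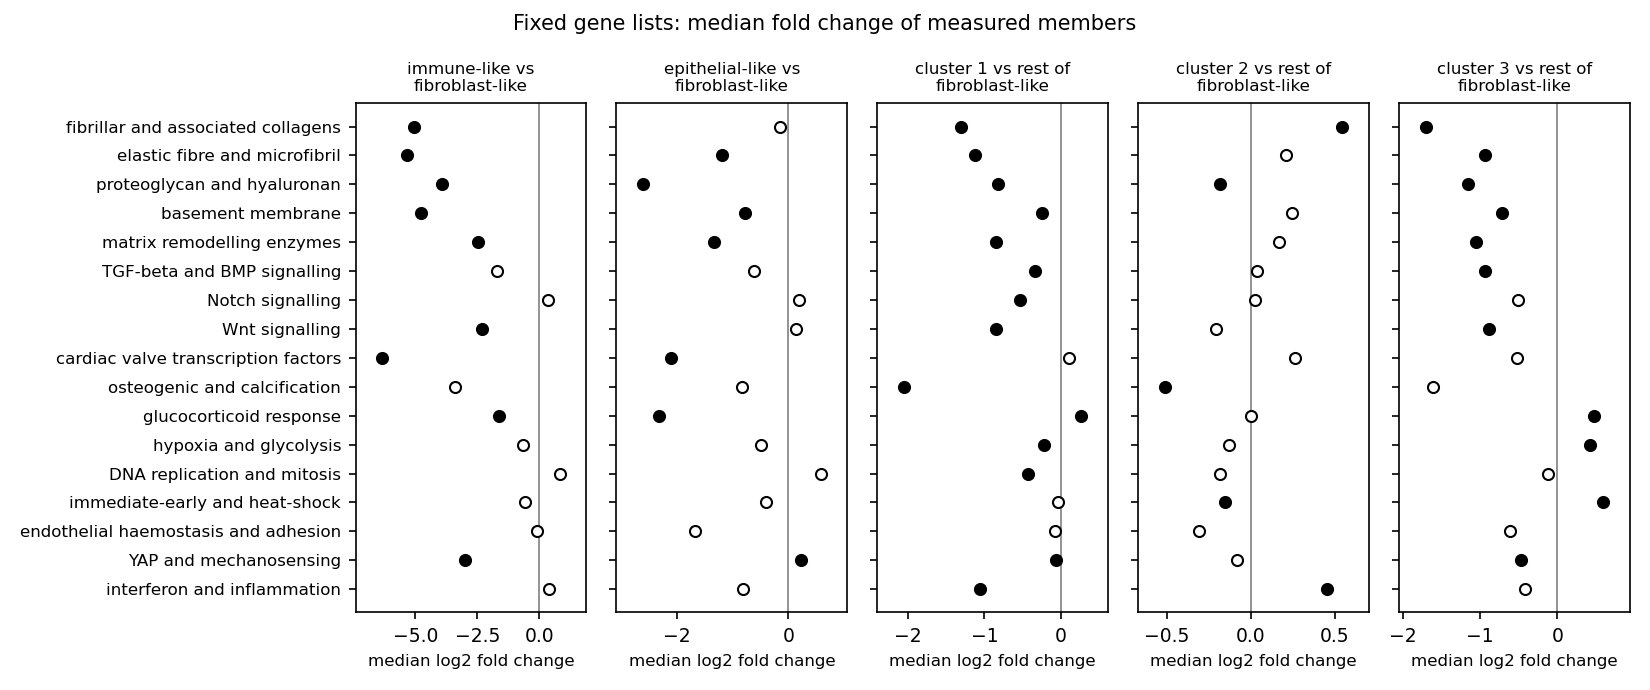
Median log2 fold change (linear axis) of the measured members of the 17 fixed gene lists in the 5 comparisons, filled where camera with its preset correlation called the list (adjusted p under 0.05) and open where it did not. The collagen list was lower in immune-like cells, cluster 1 and cluster 3 and higher in cluster 2, and no list in any comparison held with an estimated correlation.

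Within the fibroblast-like class, the 3 largest clusters were each compared with the remaining cells of the class to describe how these cells differ. The remaining cells held the other large clusters and clusters 7, 8 and 10, which were not compared themselves. A gene lower in each of the 3 largest clusters was therefore higher in the pool of clusters 7, 8 and 10. Such a gene does not show a separate fall in each cluster. Cluster 1 (16.2% ± 4.83 of all cells, led by PDE1C, PRLR and GREB1L) had lower levels of many matrix list members. MGP stood at 4.12 ± 2.65 CPM in cluster 1 against 754 ± 351 CPM in the rest, 168-fold lower (log2 fold change -7.40 ± 0.33, SE), and SFRP2, a secreted modulator of Wnt signalling (ENSG00000145423, chromosome 4, 153780592 to 153789120), was 321-fold lower (-8.33 ± 0.22). The transcription factor PRRX1 was 65.4-fold lower, the endothelin receptor gene EDNRA 54.2-fold and IGFBP7, an insulin-like growth factor binding protein, 36.0-fold (7.86 ± 2.29 against 292 ± 76.9 CPM). TSHZ2, PENK and EGFL6 were 25.5-, 21.2- and 19.5-fold lower. Genes that were higher differed less: the noncoding gene DIRC3 stood at 578 ± 21.6 against 119.9 ± 7.08 CPM (4.97-fold), and LINC00472, CLSTN2, NIBAN1 and LINC02388 were 4.42-, 3.82-, 3.17- and 3.09-fold higher.

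Of 20 elastic fibre genes 17 were lower in cluster 1 and 1 higher, with ELN (ENSG00000049540, chromosome 7, 74027789 to 74069907) 104-fold and LTBP1, a latent TGF-beta binding protein, 14.5-fold lower. Of 17 collagens 12 were lower and 0 higher (COL14A1 9.66-fold). Of 20 proteoglycan genes 12 were lower and 3 higher (BGN 89.2-fold, OGN 71.8-fold). Of 16 basement membrane genes 8 were lower and 2 higher (LAMA4 86.3-fold). Of 28 matrix enzymes 17 were lower and 1 higher (MMP11 54.1-fold, MMP2). Of 21 Wnt genes 12 were lower and 4 higher. Of 28 TGF-beta and BMP genes 10 were lower and 4 higher (the BMP antagonist GREM1 81.6-fold lower). Of 11 Notch genes 7 were lower (HEY1 54.4-fold) and 1 higher (NRARP 2.31-fold, not passing without the library block). Of 21 interferon and inflammation genes 12 were lower and 2 higher, with the chemokines CCL2 and CXCL1 13.2- and 8.73-fold lower. Of 23 YAP genes 9 were lower and 3 higher (PIEZO2 47.1-fold lower). Of 12 osteogenic genes 7 were lower and 3 higher. Of 23 hypoxia genes 9 were lower and 1 higher (SLC2A3 4.13-fold lower). Of 17 DNA replication genes 5 were lower and 1 higher. Of 20 glucocorticoid response genes 7 were higher, 1 was lower and 12 did not pass, and camera called this list as higher at its preset correlation but not with an estimated correlation (Benjamini-Hochberg adjusted p = 0.416). Those higher included PDK4, a kinase that restrains glucose oxidation (1.88-fold higher, 569 ± 44.9 against 315 ± 50.7 CPM), and ADARB1 (1.80-fold). Not called by camera were the immediate-early genes (6 lower, 2 higher of 21; IER3 lower), the endothelial genes (5 lower, 3 higher of 11; CAV1 3.27-fold lower) and the valve transcription factors (10 lower, 7 higher of 25; KLF2 9.11-fold lower), whose median (0.11) pointed up and whose mean (-0.46) and test pointed down.

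In cluster 1, 2223 of 7841 genes passed (1109 higher and 1114 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), from 9991455 to 12917510 UMIs per library. For SFRP2 the adjusted p of the edgeR test (Benjamini-Hochberg) was 8.3e-07; lower values in 3 of 3 libraries were a condition of its naming. Adjusted over the list alone, higher and lower counts became 1 and 12 for collagens, 4 and 12 for proteoglycans, 2 and 17 for matrix enzymes, 5 and 12 for TGF-beta, 5 and 13 for Wnt, 9 and 10 for valve transcription factors, 8 and 1 for glucocorticoid, 3 and 9 for hypoxia, 1 and 8 for DNA replication and 2 and 14 for interferon genes, with no difference in the others. Camera with its preset correlation called 13 lists as lower and the glucocorticoid list as higher. None of the 14 held, with adjusted p = 0.113 with an estimated correlation for the collagen, elastic fibre, matrix enzyme, Wnt and interferon lists and up to 0.416 for the hypoxia and glucocorticoid lists (camera, Benjamini-Hochberg).

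Cluster 2 (10.8% ± 0.191 of all cells, led by PROK1, PRR16 and MGST1) had its largest named upward differences in APOE and APOC1. APOE, a lipid carrier (ENSG00000130203, chromosome 19, 44905754 to 44909393), stood at 3320.0 ± 317 CPM against 362 ± 31.7 CPM in the rest of the class, 9.41-fold higher (log2 fold change 3.23 ± 0.10, SE), and APOC1 at 222 ± 37.9 against 31.8 ± 3.27 CPM (7.15-fold). IL1RL1, the interleukin-33 receptor, was 6.34-fold higher, DIO3, which inactivates thyroid hormone, 6.75-fold, and the axon guidance receptor gene ROBO2 5.07-fold. PENK and the sulfatase gene SULF1 were 25.9- and 11.2-fold lower, and ALKAL2, SELENBP1 and CELF2 6.53-, 6.46- and 6.02-fold. MGP (21.9-fold), PRRX1 (24.2-fold) and SFRP2 (19.5-fold) were lower in cluster 2 as they were in cluster 1. In both cases the rest of the class held clusters 7, 8 and 10.

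Matrix genes went both ways in cluster 2. Of 16 collagens 8 were higher and 3 lower, with COL6A3 at 239.9 ± 71.1 against 62.1 ± 22.1 CPM (4.01-fold higher) and COL12A1 3.29-fold lower. Of 20 proteoglycan genes 10 were lower and 6 higher, with OGN and ASPN 35.3- and 20.9-fold lower. Of 20 interferon and inflammation genes 11 were higher and 1 lower (CXCL1 3.49-fold, IL11 2.79-fold higher). Of 13 osteogenic genes 5 were lower and 1 higher (PDPN 1.75-fold lower). Of 21 immediate-early and heat-shock genes 10 were lower and 1 higher (HSPH1 1.78-fold, EGR1 1.67-fold lower). Lists that camera did not call had 7 higher and 5 lower of 20 elastic fibre genes (ELN 6.66-fold and MFAP5 6.68-fold lower), 7 higher and 3 lower of 16 basement membrane genes (COL15A1 5.63-fold higher, LAMA4 2.97-fold lower) and 9 higher and 9 lower of 28 matrix enzymes (MMP16 3.23-fold higher, MMP11 7.31-fold lower). Of 25 valve transcription factors 10 were higher and 7 lower (NR2F1 3.22-fold higher). Of 28 TGF-beta genes 7 were higher and 8 lower (ID1 2.43-fold, ID3 2.41-fold lower). Of 22 Wnt genes 4 were higher and 8 lower. Of 12 Notch genes 2 were lower (HES1 1.33-fold). Of 20 glucocorticoid genes 6 were higher and 4 lower, but 5 and 6 scaled by library totals (MT1X 1.91-fold and MT1M 2.46-fold higher). Of 23 hypoxia genes 3 were higher and 4 lower (HK2 2.64-fold higher, ADM 1.40-fold lower). Of 23 YAP genes 3 were higher and 6 lower (PIEZO2 6.25-fold, CCN2 2.49-fold lower). Of 11 endothelial genes 2 were higher (VCAM1 3.51-fold, TFPI 1.75-fold) and 3 lower. Of 18 DNA replication genes 1 was higher and 1 lower.

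In cluster 2, 1918 of 7761 genes passed (924 higher and 994 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 1172 passed without the library block and 1269 with the DESeq2 Wald test; MFAP5, LAMA4, HES1, MT1M, ADM and EGR1 did not pass without the block. For APOE the adjusted p of the edgeR test (Benjamini-Hochberg) was 2.2e-07, with higher values in 3 of 3 libraries. Without the filter on low counts the share of higher genes among those called was 37.4% instead of 48.2%. Adjusted over the list alone, higher and lower counts became 8 and 4 for collagens, 7 and 10 for proteoglycans, 13 and 10 for matrix enzymes, 9 and 8 for TGF-beta, 5 and 8 for Wnt, 10 and 8 for valve transcription factors, 2 and 6 for osteogenic, 6 and 6 for glucocorticoid, 3 and 8 for hypoxia, 1 and 0 for DNA replication, 4 and 6 for YAP and 12 and 2 for interferon genes, with no difference in the others. Camera with its preset correlation called the collagen and interferon lists as higher and the proteoglycan, osteogenic and immediate-early lists as lower, the last not with DESeq2 size factors (camera, Benjamini-Hochberg adjusted p = 0.0506). None of the 5 held, with adjusted p = 0.578 with an estimated correlation for 4 of them and adjusted p = 0.732 with an estimated correlation for the collagens (camera, Benjamini-Hochberg). The median pointed up and the mean down for the elastic fibre (0.21 and -0.12), matrix enzyme (0.17 and -0.25), valve transcription factor (0.26 and -0.15), TGF-beta (0.04 and -0.02) and Notch (0.03 and -0.25) lists, with the tests of the first 4 pointing up, and the endothelial list had a median of -0.31 and a mean of -0.62 with a test that pointed up. With library totals the medians of the TGF-beta and Notch lists lay below 0.

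Cluster 3 (9.47% ± 5.60 of all cells; 50, 196 and 212 cells per library) was compared in the same way. PNMT, the enzyme that makes adrenaline from noradrenaline (ENSG00000141744, chromosome 17, 39667981 to 39670475), stood at 5897 ± 76.5 CPM against 2596 ± 259 CPM in the rest of the class, 2.93-fold higher (log2 fold change 1.55 ± 0.07, SE). SELENBP1 was 3.57-fold higher (250.4 ± 24.0 against 91.5 ± 25.5 CPM), BEX1 3.08-fold, C1orf112 2.87-fold and the glutathione-cleaving enzyme gene GGT5 2.82-fold. SAA1 and SLPI, which took part in the clustering and so are only described, stood at 43502 ± 7653 and 28883 ± 2029.9 CPM. Both were abundant outside cluster 3 as well. With libraries pooled, SAA1 stood at 40648 CPM in cluster 3 and 12206 CPM in all other cells of the tissue. SLPI stood at 29571 and 8479 CPM. Outside the lists and at 50 CPM or more on a side, the lowest genes were EDNRA (50.3-fold lower, -5.65 ± 0.19) and TSHZ2 (37.3-fold). PRKG1, a kinase activated by cyclic GMP (28.1-fold), SULF1 (24.8-fold) and ROR1 (17.9-fold) followed. The nuclear noncoding RNA MALAT1 made up 0.204% ± 0.0210 of UMIs in cluster 3 and 1.94% to 2.78% in clusters 1, 2, 7 and 8 of the class, and against cluster 1 coding genes of long genomic span (over 65605 bases) had a median log2 ratio of -0.77 to -0.83 per library and those of short span (up to 20313 bases) of 0.14 to 0.20. This difference in RNA makeup went along with each list described next. TMM scaling raised the median log2 fold change of this comparison by 0.367 against library totals, a setting chosen after seeing the data. Folds thus tend to be larger upward and smaller downward than the ratios of the CPM.

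Of 17 collagens 14 were lower in cluster 3 and 2 higher (COL14A1 12.8-fold, COL12A1 11.7-fold lower). Of 20 elastic fibre genes 14 were lower and 6 higher (LTBP1 53.0-fold, ELN 24.7-fold lower). Of 21 proteoglycan genes 14 were lower and 4 higher (OGN 35.0-fold, VCAN 34.2-fold lower). Of 16 basement membrane genes 11 were lower and 3 higher (LAMA4 42.5-fold lower). Of 28 matrix enzymes 19 were lower and 8 higher (ADAM12 7.76-fold lower). Of 29 TGF-beta and BMP genes 18 were lower and 5 higher, with INHBA, an activin subunit, 19.1-fold lower. Of 21 Wnt genes 15 were lower and 1 higher (SFRP2 37.5-fold, RSPO3 15.8-fold lower). Of 23 YAP genes 16 were lower and 4 higher (PIEZO2 68.9-fold, ANKRD1 27.1-fold lower). The counts in the lists called higher depended on this scaling. At camera's preset correlation only the hypoxia list lost its call with library totals, while with an estimated correlation none of these lists was called. Of 20 glucocorticoid response genes 13 were higher and 2 lower (median 0.47), but 7 and 7 scaled by library totals (median 0.11), with DUSP1, a phosphatase of MAP kinases, at 764 ± 186 against 420.0 ± 122 CPM (2.36-fold) and GLUL, glutamine synthetase, 2.15-fold higher. Of 21 immediate-early and heat-shock genes 15 were higher and 4 lower (10 and 4 scaled by library totals), although the named members IER3 and NR4A1 were 3.24- and 2.28-fold lower. Of 23 hypoxia and glycolysis genes 14 were higher and 7 lower, but 8 and 8 scaled by library totals, where camera did not call the list (Benjamini-Hochberg adjusted p = 0.149), with SLC2A3 and PFKP 3.57- and 3.10-fold lower. Lists that camera did not call had 7 lower and 3 higher of 12 Notch genes (JAG1 2.87-fold lower), 15 lower and 7 higher of 25 valve transcription factors (PRRX1 73.6-fold lower; called as lower with library totals and with DESeq2 size factors), 9 lower and 2 higher of 13 osteogenic genes (MGP 18.0-fold, RUNX2 3.06-fold lower), 7 lower and 3 higher of 11 endothelial genes (CAV1 3.37-fold lower), 10 lower and 4 higher of 20 interferon genes (CCL2 9.31-fold lower) and 1 lower and 2 higher of 18 DNA replication genes (4 and 0 scaled by library totals), whose median (-0.11) and mean (-0.18) pointed down and whose test pointed up.

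In cluster 3, 5354 of 7994 genes passed (2310 higher and 3044 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), from 2490433 to 10746550 UMIs per library. With library totals 1130 were higher and 4080 lower. For PNMT the adjusted p of the edgeR test (Benjamini-Hochberg) was 1.0e-10, with higher values in 3 of 3 libraries. Adjusted over the list alone, 8 valve transcription factors were higher and 15 lower, and 0 DNA replication genes were higher and 1 lower, with no difference in the others. Camera with its preset correlation called 8 lists as lower and the glucocorticoid, immediate-early and hypoxia lists as higher. None of the 11 held, with adjusted p = 0.329 to 0.381 with an estimated correlation (camera, Benjamini-Hochberg). Nor was the valve transcription factor list, called as lower with library totals and DESeq2 size factors, called with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.329).

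**Figure D3:**
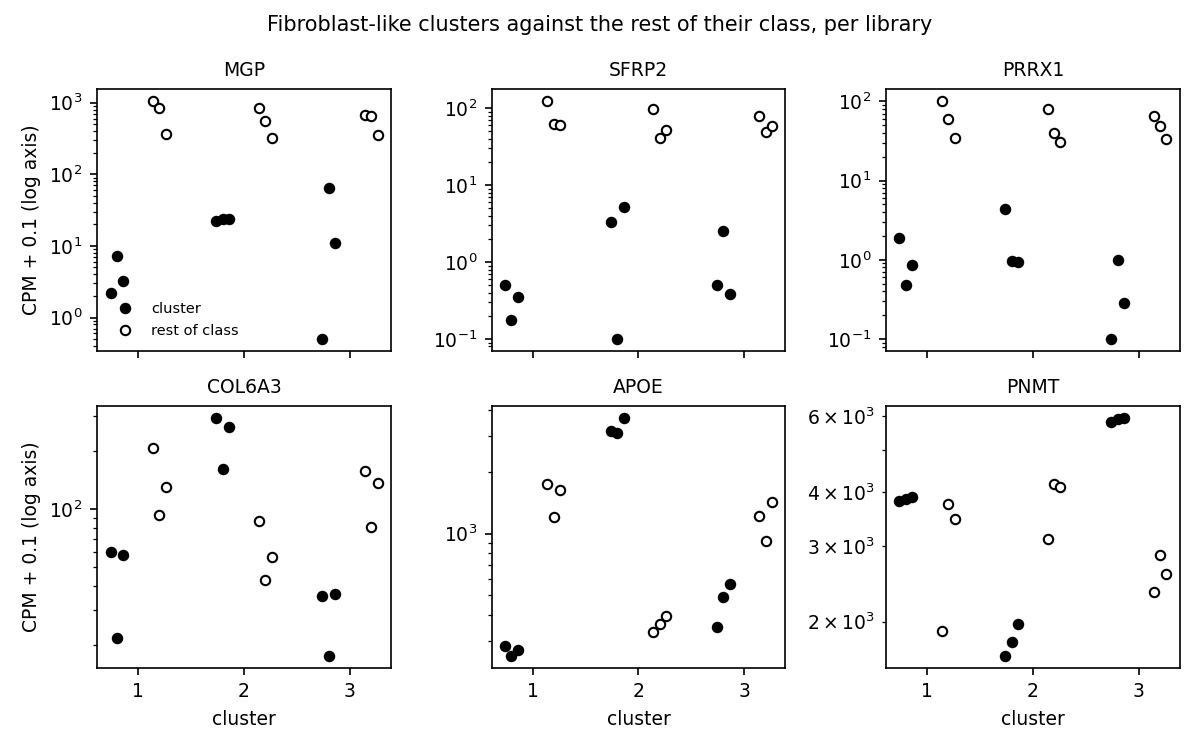
CPM + 0.1 (log axis) of 6 genes in clusters 1, 2 and 3 of the fibroblast-like class (filled) and in the remaining cells of the class (open), 1 point per library. MGP, SFRP2 and PRRX1 were lower in each of the 3 clusters than in its remaining cells, which always held clusters 7, 8 and 10. COL6A3 and APOE were higher in cluster 2, and PNMT was higher in cluster 3.

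As a check of the tests, fibroblast-like cells were divided at random within each library. Such a division takes no account of expression, so it cannot show false calls that come from clustering the same cells. The edgeR quasi-likelihood test called 0 of 8022 genes between these parts, with 329 at unadjusted p under 0.05, but camera with its preset correlation called 2 of 17 lists, so a call by camera alone is weak evidence in this design. In simulated data with known changes, the share of false calls was 9.14% in the immune-like comparison, 8.65% in the epithelial-like comparison and 4.30%, 11.2% and 5.46% for clusters 1, 2 and 3, above the nominal 5% in 4 of 5. These shares rest on 8 to 23 false calls per comparison, with far fewer genes changed than were called in the real data.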

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

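Of the shares and counts that answer a comparison, 89 of 118 values under other settings and 47 of 48 without a replicate stayed the same (within 1 SD, or within 1.5 times for counts). For shares, leaving 1 of 3 libraries out moves a mean by less than 1 SD whatever the values, so those leave-outs do not test stability. The share of fibroblast-like cells was 37.1% with mitochondrial limit 25%, where more cells were kept (5162 against 4835) but fibroblast-like cells fell from 2228 to 1876 and unnamed cells rose from 485 to 1041, so clusters lost their name, and 32.2% with clusters 3 and 7 left out, a setting chosen after seeing the data. The share of immune-like cells was 27.3% with mitochondrial limit 10% and 40.1% at 25%. At 10%, 531 cells were removed but immune-like cells fell by 798 and unnamed cells rose to 869, so part of the fall was a loss of names. The share of epithelial-like cells was 4.28% with doublets kept, where 64 cells were added, epithelial-like cells rose by 84 and unnamed cells fell to 410, so cells were also named anew. The share of unnamed cells was 15.2% and 11.1% at resolution 0.3 and 1.0, 7.99% with another gene division, 19.0% centred per library, 20.3% and 20.2% with mitochondrial limits of 10% and 25%, and 8.34% with doublets kept. With settings chosen after seeing the data it was 2.69% with clusters led by another class's genes included, 24.7% with clusters 3 and 7 left out and 10.3% with clusters 10 and 16 left out. MKI67 was found in 1.40% of cells at 2 UMIs and 3.07% without thinning, and TOP2A in 1.78% and 6.27%, as the threshold and depth would set.

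Lists called fell to 0 in each of the 5 comparisons (0, 0, 0, 0 and 0) with camera's correlation estimated. With fry 16 lists were called for immune-like cells, 12 for epithelial-like cells and 0 for cluster 2. For cluster 2, without the replicate block 1172 genes and 2 lists were called, and 1269 genes with the DESeq2 Wald test. In the other comparisons, no replicate block gave 6828 (immune-like), 3405 (epithelial-like), 1547 (cluster 1) and 5076 (cluster 3) genes. Genes called for epithelial-like cells ranged from 1938 (without replicate 3, the library with most of these cells) to 3115 without a replicate. With another gene division, counts are over the genes tested in both, 3522 against 3574 for immune-like and 1698 against 1755 for epithelial-like cells.

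Of the named genes, 1824 of 1834 values under other settings and 635 of 636 without a replicate kept direction and call. These genes were picked from the main fit for passing with large fold changes, so such agreement was largely given by their choice. MT1M reversed in epithelial-like cells with doublets kept (log2 fold change 1.66), where the class held other cells as well. With library totals, a setting chosen after seeing the data, no named gene changed direction or call. Of the list tests, 337 of 425 and 222 of 255 kept both. Lists that changed direction were called in neither setting; with Benjamini-Hochberg adjusted p they were, for fry, Wnt in epithelial-like cells (0.383) and DNA replication in cluster 3 (0.544), and without the replicate block the endothelial list in cluster 2 (0.563). Without a replicate (camera, adjusted p, lowest to highest), they were the endothelial list in immune-like (0.679 to 0.974) and epithelial-like cells (0.520 to 0.974), and in cluster 2 TGF-beta (0.731 to 0.963), hypoxia (0.242 to 0.963), DNA replication (0.647 to 0.900) and endothelial (0.371 to 0.833). Of tissue levels, 245 of 292 values under other settings and 219 of 219 without a replicate stayed within 1 SD. With 3 libraries, leaving 1 out moves a mean by less than 1 SD whatever the values, so the 219 do not test stability. The 47 that moved were all among the 73 means over cells, which weigh shallow immune-like cells more, so most levels depended on that weighting. Other causes were not tested.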

Other observations

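The comparisons of immune-like clusters, the tests of free RNA, of the cell filters and of bare nuclei (the first and last in a second form), and the test by genomic span in cluster 3 were chosen after the results were seen. Cluster 4 (8.95% of cells) had HLA-DPB1, an MHC class II gene, at 203 ± 36.3 against 3.12 ± 0.977 CPM in the rest of the class (log2 fold change 5.99 ± 0.19, SE, n = 3 libraries) and SPP1 at 4450.5 ± 2829.6 against 679 ± 217 CPM (2.51 ± 0.16). LYVE1, a receptor of resident tissue macrophages, was lower there (-3.21 ± 0.17; 121 ± 48.8 against 1031 ± 128 CPM). Cluster 0 (21.5%), led by F13A1, MRC1 and CD36, was low in HLA-DRB1 (-6.70 ± 0.21) and TNFAIP3 (-2.45 ± 0.12) and high in the transcription factor gene MEF2C (1.94 ± 0.11), and 13 of 17 interferon and inflammation genes were lower and 0 higher. Cluster 5 (8.46%), led by IL1B, was high in SERPINB2 (4.15 ± 0.40), CXCL2 (3.05 ± 0.18) and ICAM1 (2.36 ± 0.12), with 9 of 16 interferon and inflammation genes higher and 2 lower (8 and 5 scaled by library totals). CHI3L1 had 0 UMIs in cluster 5, at least 159.9-fold lower. It was low in cluster 0 as well, with 2 UMIs against 2084 in the rest of the class (a ratio of 820, counting interval 227 to 6777), so this was not particular to cluster 5.

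In these comparisons 1725 (cluster 0), 2048 (cluster 4) and 1390 (cluster 5) genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without the replicate block these were 1050.0, 1683 and 879, with the DESeq2 Wald test 816, 1163 and 721, and for cluster 5 771 genes passed without replicate 3. In cluster 5, 820 genes were higher and 570 lower, but 600 and 1059 scaled by library totals, a setting chosen after seeing the data. Camera with its preset correlation called 7, 6 and 2 lists, of which 0 held with an estimated correlation (lowest Benjamini-Hochberg adjusted p 0.247, 0.469 and 0.568). Cluster 6, unnamed, expressed TNNT2 at 257 ± 44.8 CPM and THY1 at 337 ± 17.0 CPM with MYH6 at 2.79 CPM. Cluster 9, unnamed and cycling, expressed MKI67 at 119 ± 41.6 CPM and ACTA2 at 754 ± 137 CPM.

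The high share of immune-like cells in tissue made from valve cells was weighed against artefacts. Free RNA from few immune cells would leave fibroblast transcripts near their fibroblast-like level in the immune-like class. Over 14 collagens that took no part in the clustering, the median reached at most 3.178% of that level in a library, which argues against this cause. Filters that removed fibroblast-like cells could also raise the share. Before these filters 39.16% of barcodes had more immune than fibroblast marker UMIs and 57.23% had more fibroblast ones, so many immune-like barcodes were present already. The class shares, 40.6% and 46.8%, come from named clusters and not from this balance, which was not taken in the kept cells. How far the filters moved the share of immune-like cells is thus not shown, and loss of cells before the barcodes were listed was not tested. With called doublets kept the share was 40.1%, so these did not set it, while doublets that were missed, the gate of the sort and the source of these cells, whether differentiation or another origin, were not tested and stay open.

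Cluster 3 is low in MALAT1, and loss of nuclear RNA is offered as a hypothesis, on which 3 tests point different ways. The first, set before its value was seen, predicted that noncoding genes fall, that coding genes move little and that few of them are 4-fold higher than in the rest of the class. Only 6 were, but 533 of 6576 coding genes were at least 4-fold lower, so the prediction was met in part only. Nuclear RNA also holds unspliced coding transcripts, so this test does not decide. A condition added later took cluster 1 as reference and set over 100 coding genes at least 4-fold lower as speaking against the hypothesis. There were 42 of 6471 in all libraries. Loss of unspliced coding transcripts would lower coding genes too, so this count does not decide either. The second, also set before, asked that noncoding genes fall below coding genes by over 0.5; the smallest difference was -0.2601, so it was not met. The last, chosen after these outcomes and the names of the lowest genes were seen, with cluster 1 as reference, found genes of long span lower than short ones, with a difference of -0.9107 in median log2 ratio in the library where it was smallest (mean -0.94, -1.47 and -1.02 against clusters 2, 7 and 8), which fits a loss of unspliced transcripts. Lower transcription of long genes could give the same pattern, and whether intronic reads were counted is not given in the sources used here, so the cause stays open.

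Cluster 10 (2.12% of cells) held 11.5% MALAT1 and 1.91% ribosomal protein transcripts, against 19.4% to 24.4% ribosomal protein in the other fibroblast-like clusters. Bare nuclei would carry little mitochondrial RNA, and its share was uneven here: 7.39%, 8.33% and 5.54% of pooled UMIs per library, 2.90%, 9.38% and 3.55% in the median cell and 0.639%, 0.486% and 0.821% in the lower quartile. The median cell differed from that of the highest other cluster of the class by -1.251 percentage points in the lowest library and lay above it in replicate 2, so bare nuclei are neither borne out nor excluded and could make up part of the cluster. Damaged cells that lost cytosolic RNA could make up another part: 5 cytosolic transcripts stood at no more than 36.25% of their level in the lowest other cluster, but bare nuclei would show this too, so the 2 explanations cannot be told apart. The number of genes called for immune-like cells was 6896 with clusters 10 and 16 left out, a setting chosen after seeing the data, against 6895.

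The other groupings of the 6 sums per comparison were tested as well. The sums form 3 library pairs, and only splits that part all 3 pairs, 4 with the real one, can be set beside it in the blocked test. Of these 4 splits only the real one (1, 1, 1, 1 and 1) called as many genes, 6895 for immune-like cells, 3263 for epithelial-like cells and 2223, 1918 and 5354 for clusters 1, 2 and 3, and the highest other split called 0. With 4 splits a share under 0.05 cannot be reached. Even with held-out genes, the groups came from the expression of these same cells, so the real split was all but bound to call the most genes. Its rank is therefore no evidence for the grouping. The remaining 6 splits part 1 pair only and break the pairing; they also called 0 and are not counted.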
